A study of Mus musculus with 6 samples.

How the data were processed

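Granulocyte-monocyte progenitors were sorted from mouse bone marrow straight into extraction buffer, RNA was extracted with the PicoPure kit and libraries followed standard Illumina protocols, per the labels' protocols. The design has 6 libraries, 3 from sham-operated C57BL/6 mice and 3 from mice with hindlimb ischemia, and these are all the samples of the series. The labels do not state that each replicate is a separate animal, so the p-values measure only the spread between these samples.

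The deposited all-gene table holds TPM values per library for 24205 genes, per the file headers, and each TPM column sums to 1000000. It also holds the authors' log2 fold change and the authors' adjusted p-value per gene, per the file headers. A short list of 34 genes repeats the deposited log2 and p-value columns and adds the authors' gene length, start and end in base pairs, per the file headers. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, the gene annotation and the test behind the p-values are not given in the sources used here, nor is whether reads were counted by strand. The header does not name the direction of the deposited log2 fold change. Across genes its Spearman correlation with log2 of hindlimb ischemia over sham from the TPM values was -0.98, so it is sham over hindlimb ischemia, and the report turns its sign. The authors' p-value is NA for 8458 genes. The 6 per-sample TPM columns of the short list repeat the all-gene table and were not used here.

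TPM values keep no depth by themselves. Multiplied by the exon-union length of GENCODE M21, they fall on whole multiples of 1 value per library, the worth of 1 read. This gave whole reads in all 6 libraries for 14448 genes (59.7%), within a tolerance of 0.001 reads. For the other 9757 genes the smallest length that made all 6 values whole within 1e-05 reads was taken, so their reads are whole up to a common factor. The totals recovered were 35054164, 32548024 and 37130484 reads for sham replicates 1 to 3, and 32755589, 35718887 and 41624579 reads for hindlimb ischemia replicates 1 to 3. Of the genes with the smallest unadjusted p, the small RNA genes rest on at most 35 reads in any library. No 2 libraries agreed within sampling noise, with chi-square values per gene from 13.2 to 118.2 over the pairs. Gene positions are those of GENCODE M21 on GRCm38, the same assembly as mm10. For the 34 genes of the short list, 30 starts and 27 ends equal those given by the authors.

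The design, fixed before the data were examined, assumed read counts and named a count-based test, with a fallback for normalized values. Because the deposited unit was TPM, the fallback was used. Genes with at least 1 TPM in at least 3 libraries were kept (13787), log2(TPM + 1) was taken, and limma-trend was fitted with robust empirical Bayes variance and no covariate, with 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. On the log2(TPM + 1) scale, fold changes of genes at a few TPM are smaller than the ratio of their means. The 25 gene lists, fixed beforehand, covered bone marrow cell types, the cell cycle, metabolism, stress, inflammation, chromatin, receptors and secreted factors. The 24 with at least 5 tested members were tested with camera at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Separation of the groups was tested by an exact permutation of the 10 splits on Euclidean distances over the 500 most variable genes. The correction for GC content and transcript length removed from each library's deviations a loess curve (span 0.3) on GC content and then one on log2 transcript length.

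Genes named in the text follow a rule fixed beforehand. It takes the 12 genes with the smallest unadjusted p in each direction, since 0 passed the threshold, and the 2 members of each list with the smallest p. It adds Mpo, Elane, Irf8, Csf1r, Cd34 and Kit as checks of the sorted population, and the 3 highest and 3 lowest genes of the authors' short list. Unannotated models and pseudogenes were counted but not named. The rule gave 74 genes, of which 2 are not reported here. Other list members, and genes called under single alternatives, are named as examples chosen after their values were seen.

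Alternatives fixed beforehand were quantile normalization, limma without a trend, no filter, a mean of at least 5 TPM, pseudocounts of 0.1 and 5, a threshold of 0.2, the replicate number as a block and leaving out each library. Size factors, protein-coding genes only, limma-voom on recovered reads, array weights, the GC and length correction and its combinations with the block were chosen after seeing the data. The fit was tested on simulated reads for hindlimb ischemia versus sham, drawn for 13789 genes with a dispersion of 0.0136. It recovered 27 of 67 genes changed 1.5-fold (40.3%), 67 of 67 changed 2-fold (100%) and 66 of 66 changed 4-fold (100%), with 20 false calls. The false calls were a larger share of all calls than the threshold of 0.05. With nothing changed the fit made 4 calls. The simulation therefore does not show that the fit holds its threshold. A list shifted by -0.4 was called and 0 other lists were, and a simulated GC trend with r of 0.527 was reduced to 0.002. The simulated reads were drawn independently for each gene, with 1 dispersion and no GC or length trend between libraries. The shares recovered need therefore not hold for the real libraries. There Gfi1b, with a log2 fold change of -1.01, had an adjusted p of 0.417 by limma-trend. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.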

Results

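Granulocyte-monocyte progenitors, the bone marrow cells from which neutrophils and monocytes arise, were profiled by bulk RNA sequencing in C57BL/6 mice. The animals had undergone either hindlimb ischemia, in which the blood supply of a hind leg is interrupted, or a sham operation. Each of the 2 groups held 3 libraries. Expression was given as TPM, which scales reads by gene length and by the library's total, for 24205 genes, and 13787 genes with at least 1 TPM in at least 3 libraries were tested. Pairs of TPM values joined by "against" give the sham mean first and the hindlimb ischemia mean second. The reads recovered from the TPM values were 35054164, 32548024 and 37130484 for sham replicates 1, 2 and 3, and 32755589, 35718887 and 41624579 for hindlimb ischemia replicates 1, 2 and 3. Across genes, libraries correlated with r from 0.985 to 0.993 within sham, from 0.978 to 0.992 within hindlimb ischemia and from 0.973 to 0.992 between the groups.

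The comparison asked whether ischemia in a distant limb alters the transcriptome of these progenitors. By camera with a preset correlation, immediate early and heat shock genes such as Hspa8 and Jun were lower as a list after hindlimb ischemia (adjusted p = 0.8 with an estimated correlation). Erythroid and megakaryocyte genes, among them the globins and Gfi1b, were lower as a list in the same test (adjusted p = 0.269 with an estimated correlation). Unfolded protein response and inflammatory genes were lower, and mitochondrially encoded, nuclear oxidative phosphorylation and histone genes higher, in that test only (adjusted p = 0.897 with an estimated correlation for each). Of these 5 lists, only oxidative phosphorylation stayed past 0.05 after the GC and length correction among protein-coding genes, and none did after the correction over all genes. No single gene passed the threshold of 0.05 for the adjusted p over all genes.

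With limma-trend, 0 genes were past that threshold and 0 were past 0.2. Herpud1 had the smallest adjusted p, 0.212. At an unadjusted p under 0.05 there were 537 genes, of which 130 were higher and 407 lower after hindlimb ischemia. This count ran from 234 without hindlimb ischemia replicate 2 to 2679 without hindlimb ischemia replicate 1. For 1149 genes (8.3%) the 3 values of each group did not overlap, where chance gives 10%. The median log2 fold change of all genes was -0.09, and 69.1% of genes had a negative value. Division by median-of-ratios size factors moved that median to 0.02 and the unadjusted calls to 336 higher and 364 lower. It again left 0 genes past 0.05. For some lists the median is therefore also given relative to all genes. Limma-voom on the recovered reads gave 0 genes past 0.05 and 700 at an unadjusted p under 0.05. Limma without a trend gave 1 gene, an unannotated model, and array weights gave 1 gene, the immunoglobulin gene Igkc, which was chosen for mention after its value was seen. Leaving out hindlimb ischemia replicate 1 gave 41 genes past 0.05, 24 higher and 17 lower, and 1070 past 0.2, 307 higher and 763 lower. Leaving out replicate 2 or replicate 3 of that group gave 1 gene each past 0.05. After removal of each library's trend with GC content and transcript length among protein-coding genes, 4 genes were past 0.05: Tfrc and Gda higher, Herpud1 and Syvn1 lower. The same correction over all genes gave 0.

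**Figure D1:**
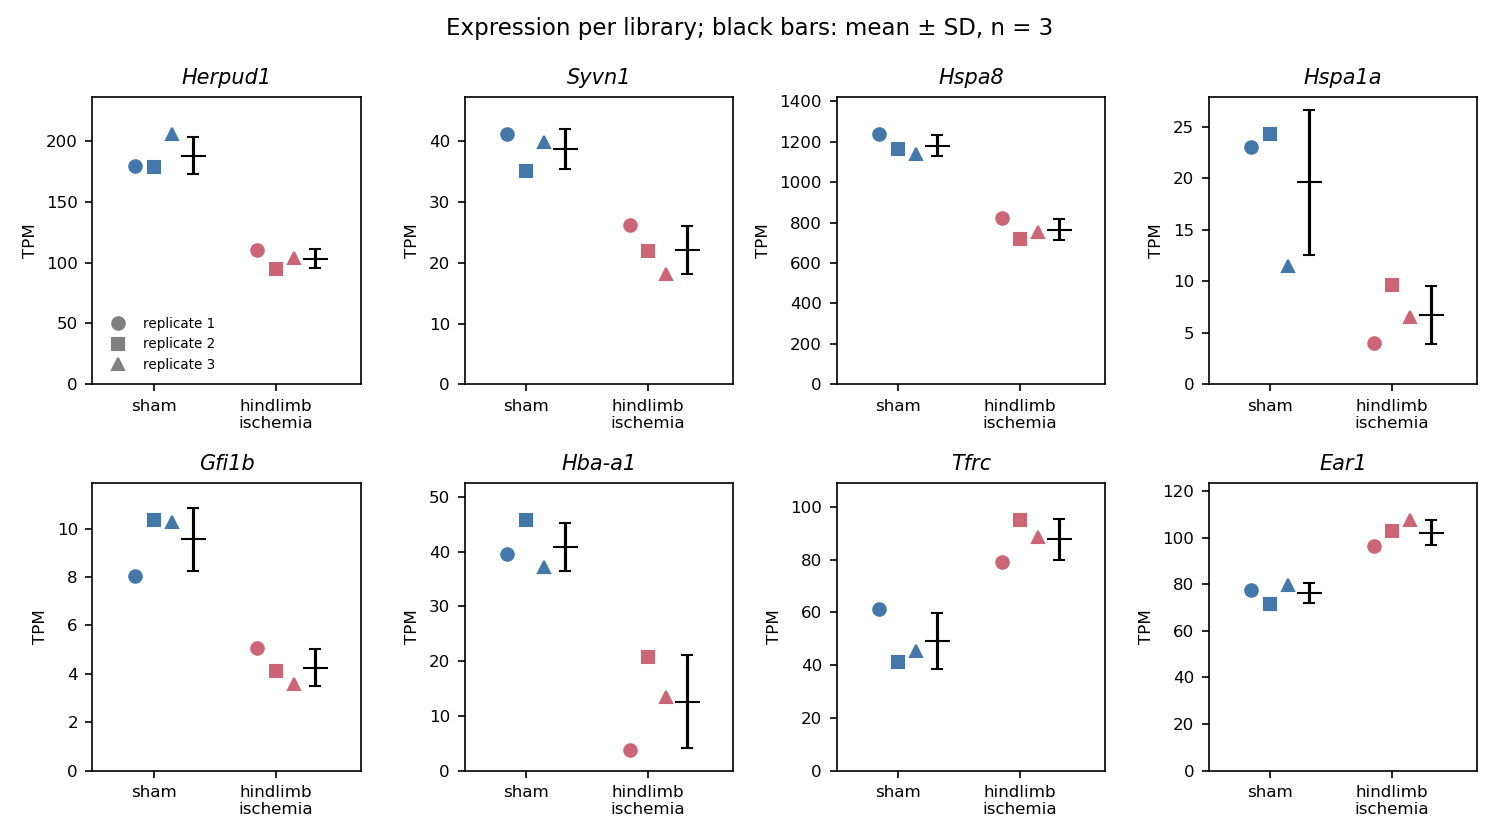
TPM of 8 genes in each library, with sham in blue, hindlimb ischemia in red, the marker shape giving the replicate number and black bars the mean and SD of 3 libraries. The groups do not overlap in any of the 8 genes; Hspa1a has the widest spread in sham (SD 7.03 TPM) and Hba-a1 in hindlimb ischemia (SD 8.48 TPM) relative to their means.

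Herpud1 (ENSMUSG00000031770, GRCm38/mm10 chromosome 8, 94386438 to 94395377), a gene of endoplasmic reticulum protein degradation, had 188 ± 15.3 TPM in sham and 103 ± 7.77 TPM after hindlimb ischemia (mean ± SD, n = 3 each), from 4383 to 9831 reads per library. Its log2 fold change was -0.86 (SE 0.13), and -0.72 (SE 0.09) with an adjusted p of 0.0381 once the GC and length trends were removed among protein-coding genes. Syvn1 (ENSMUSG00000024807, chromosome 19, 6046576 to 6053712), which encodes a ubiquitin ligase of the same pathway, had 38.7 ± 3.25 and 22.1 ± 4.02 TPM, a log2 fold change of -0.79 (SE 0.17) and a corrected value of -0.57 (SE 0.08; adjusted p 0.0475). Tfrc (ENSMUSG00000022797, chromosome 16, 32608920 to 32632794) had 49.2 ± 10.7 TPM in sham and 87.7 ± 7.89 TPM after hindlimb ischemia, from 4668 to 13604 reads. Its log2 fold change of 0.84 (SE 0.17) became 0.87 (SE 0.09; adjusted p 0.00613) after the correction. Gda (ENSMUSG00000058624, chromosome 19, 21391307 to 21473445), which encodes guanine deaminase, had 25.4 ± 3.73 and 34.5 ± 1.84 TPM and a corrected log2 fold change of 0.51 (SE 0.07; adjusted p 0.0475). The correction over all genes tested left 0 genes past 0.05, with 0.1 the smallest adjusted p, against these 4 calls among 10524 protein-coding genes. In the limma-trend fit of all 6 libraries without the correction, each of these 4 genes missed the threshold, with adjusted p of 0.212 for Herpud1, 0.605 for Syvn1 and Tfrc, and 0.874 for Gda. Without hindlimb ischemia replicate 1 the adjusted p was 0.0234 for Herpud1, 0.0372 for Syvn1 and 0.0451 for Tfrc, and with another library left out it ran up to 0.808 for Herpud1 and 1 for Syvn1 and Tfrc.

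Among the 12 genes with the smallest unadjusted p in each direction, the transcription factor genes Gfi1b and Banp had lower values after hindlimb ischemia, 9.56 against 4.25 TPM and 9.90 against 5.10 TPM. The water channel gene Aqp1 had 3.29 against 1.46 TPM, and Gem, which encodes a small GTP-binding protein, had 2.16 against 0.745 TPM. Ly6d, a lymphoid surface marker, had 2.33 against 0.267 TPM, from 1 to 50 reads per library. Higher values were seen for Ear1 (76.3 against 102 TPM), an eosinophil ribonuclease gene with close paralogs whose reads may be shared. The same held for Tgm1 (1.86 against 3.30 TPM), Oosp1 (1.80 against 3.15 TPM), Glrp1 (log2 fold change 0.50), Clu (1.27 against 2.26 TPM) and Cav2 (1.71 against 2.87 TPM). Small RNA genes were among both sets: AF357399, a snoRNA with 4 to 35 reads, had 2.73 against 8.74 TPM, and Rny1 had a log2 fold change of 0.93 from 1 to 12 reads. Of the microRNA genes, Mir3091 and mmu-mir-6942 had log2 fold changes of 0.65 and 1.29, and Mir1938 and Mir695 of -1.79 and -1.56, with at most 17 reads in any library. None of these genes was past the adjusted threshold.

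**Figure D2:**
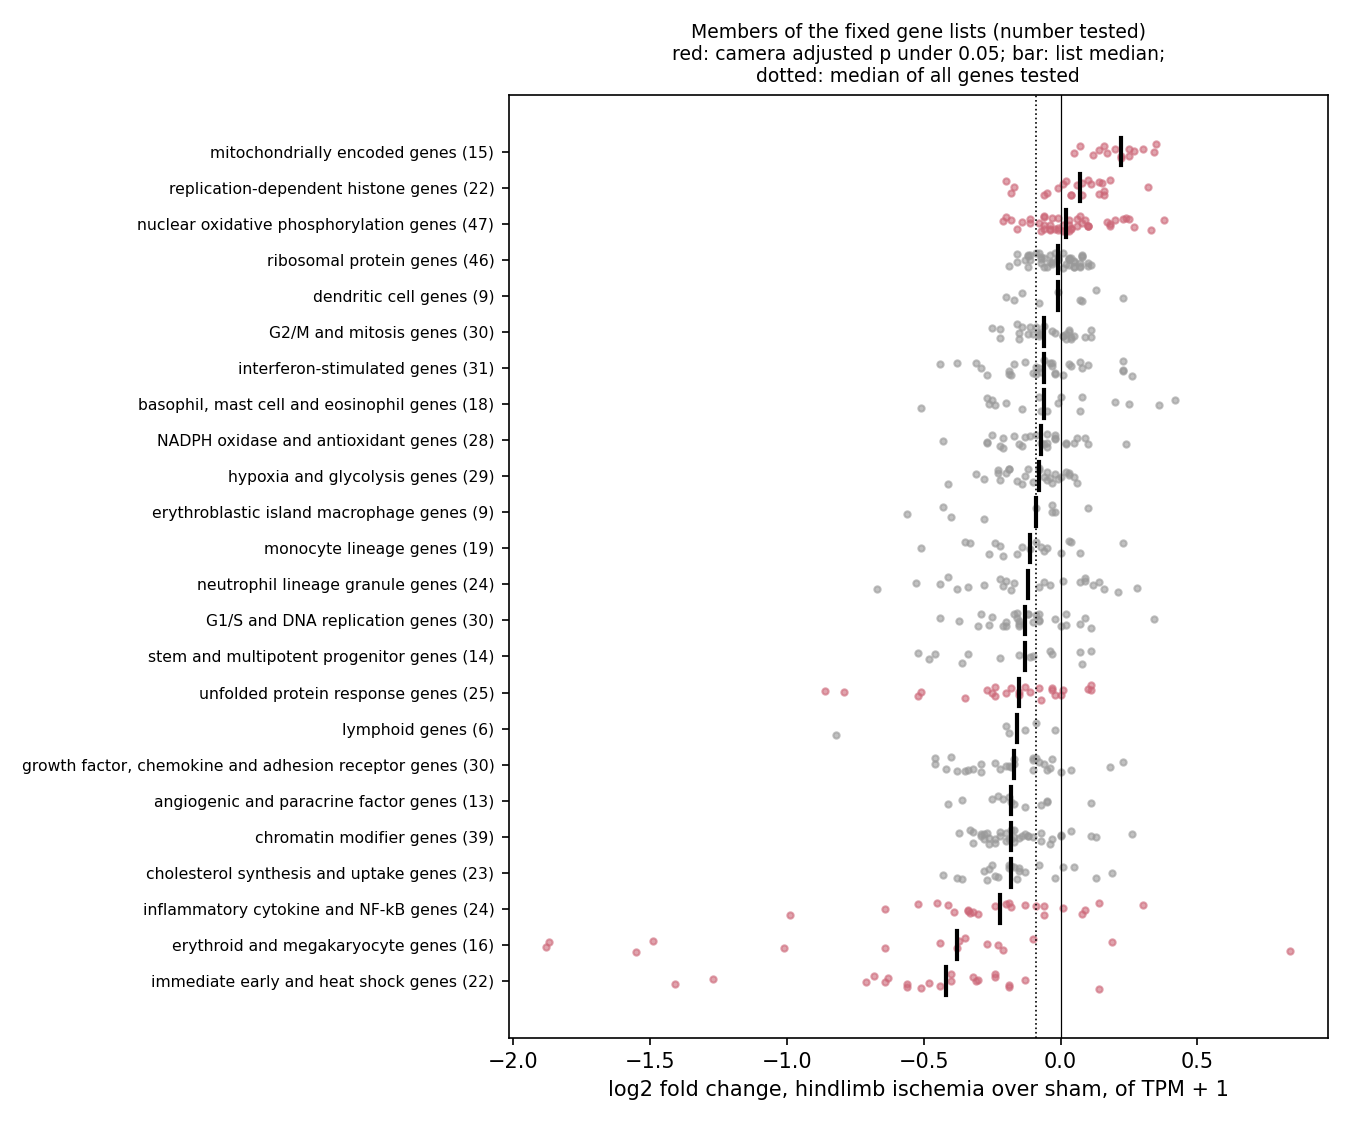
Log2 fold change of hindlimb ischemia over sham, on TPM + 1, for each tested member of 24 fixed gene lists, with a black bar at the list median, red points for lists past a camera adjusted p of 0.05 and a dotted line at the median of all genes (-0.09). The lists of immediate early and heat shock genes (median -0.42) and of erythroid and megakaryocyte genes (median -0.38) lie lowest, and the mitochondrially encoded genes (median 0.22) highest.

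Immediate early and heat shock genes fell as a list by camera (adjusted p = 7.39e-13), with a median log2 fold change of -0.42, or -0.33 relative to all genes. With an estimated correlation of 0.49 between members the call was lost (adjusted p = 0.8 with an estimated correlation). Of 22 members tested, 21 had lower means, 10 of them with groups that did not overlap. No member was past 0.05 adjusted over all genes, and 11 were lower when adjusted over the list alone. Hspa8 (ENSMUSG00000015656, chromosome 9, 40800984 to 40810087), the constitutive HSP70 gene, had 1180 ± 52.0 TPM in sham and 765 ± 52.5 TPM after hindlimb ischemia. The inducible genes Hspa1a and Hspa1b, near-identical copies between which reads may be split, had 19.6 against 6.74 TPM and 35.6 against 14.1 TPM. Among the immediate early genes, Btg2 had 31.6 against 19.2 TPM, Jun 97.5 against 60.9 TPM and Fos 69.6 against 48.5 TPM. Hsp90aa1 was the member with the opposite sign (log2 fold change 0.14). After the GC and length correction the list median was -0.30 and the adjusted p 2.78e-12.

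Erythroid and megakaryocyte genes fell as a list by camera (adjusted p = 5.18e-06), with a median of -0.38, or -0.29 relative to all genes, and a mean of -0.61. The estimated correlation between members was low, 0.03, yet the call was lost with it (adjusted p = 0.269 with an estimated correlation). The reason for this loss was not tested. Of 16 members tested, 14 had lower means, 0 were past 0.05 over all genes, and 8 passed when adjusted over the list alone, 7 lower and Tfrc higher. The globin genes, whose near-identical pairs may share reads, had the largest log2 fold changes of the list. Hba-a1 had 40.8 ± 4.42 TPM in sham and 12.6 ± 8.48 TPM after hindlimb ischemia, and Hbb-bs had 27.0 ± 3.01 and 10.1 ± 6.07 TPM. The 3 hindlimb ischemia libraries had 3.76, 20.7 and 13.4 TPM of Hba-a1. Gfi1b (ENSMUSG00000026815, chromosome 2, 28609450 to 28621982), a repressor needed for erythroid and megakaryocytic differentiation, had a log2 fold change of -1.01 (SE 0.18). Klf1 had 5.79 against 3.42 TPM, Nfe2 137 against 106 TPM and Gata1 9.06 against 6.66 TPM. The median of the 12 members other than the 4 globins was -0.31. With the GC and length correction the list median was -0.27 (adjusted p 2.62e-06).

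Unfolded protein response genes fell as a list (adjusted p = 0.0282; median -0.15, or -0.06 relative to all genes), with 20 of 25 members lower. The call was lost with an estimated correlation (adjusted p = 0.897 with an estimated correlation), and also with size factors (0.116), protein-coding genes only (0.102) and voom on recovered reads (0.137). Adjusted over the list alone, Herpud1 and Syvn1 were lower and 0 genes were past 0.05 over all genes. Ddit3 had 9.21 against 6.18 TPM, while the chaperone genes Calr (1327 against 1312 TPM) and Pdia6 (386 against 389 TPM) differed by less than 1 SD. Inflammatory cytokine and NF-kB genes fell with the same adjusted p of 0.0282 and a median of -0.22, or -0.13 relative to all genes, with 19 of 24 members lower. That call was lost with an estimated correlation (adjusted p = 0.897 with an estimated correlation), and also with quantile normalization (0.056), a mean of at least 5 TPM (0.176), protein-coding genes only (0.0817) and array weights (0.197). Adjusted over the list alone, 3 were lower, against 0 over all genes: Cxcl2 (3.19 against 1.08 TPM), Ccl4 (10.8 against 6.52 TPM) and the inhibitor gene Nfkbia (68.7 against 47.6 TPM). Both calls were lost after the GC and length correction, with an adjusted p of 0.194 and a median of 0 for the unfolded protein response, and 0.0886 with a median of -0.08 for the inflammatory list. Without sham replicate 1 the adjusted p was 0.122 and 0.203 for the 2 lists, without hindlimb ischemia replicate 3 it was 0.145 and 0.128 with medians of -0.03 and -0.10, and without sham replicate 3 it was 0.063 for the unfolded protein response.

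Mitochondrially encoded genes rose as a list (adjusted p = 5.18e-06; median 0.22, or 0.31 relative to all genes), and all 15 members had higher means. The call was lost with an estimated correlation of 0.96 between members (adjusted p = 0.897 with an estimated correlation). No member passed either over all genes or adjusted over the list alone. Their share of TPM was 4.65, 5.31 and 4.25% in sham replicates 1 to 3, and 3.63, 6.11 and 7.19% in the hindlimb ischemia replicates, so replicate 1 of that group lay below all sham libraries. mt-Nd1 had 2579 ± 297 TPM in sham and 3254 ± 854 TPM after hindlimb ischemia. After the GC and length correction the list median was 0.02 (adjusted p 0.866). Nuclear oxidative phosphorylation genes rose relative to other genes (adjusted p = 0.00549; median 0.02, 26 of 47 members higher), with Cycs at 321 against 429 TPM and Uqcrb at 401 against 516 TPM. That call was lost with an estimated correlation (adjusted p = 0.897 with an estimated correlation), and also with quantile normalization (0.307), no filter (0.0914) and array weights (0.817). Replication-dependent histone genes rose likewise (adjusted p = 0.0155; median 0.07, 16 of 22 members higher), with Hist2h2ac at 26.7 against 33.2 TPM. That call was lost with an estimated correlation (adjusted p = 0.897 with an estimated correlation), and also with quantile normalization (0.056), no filter (0.0975), size factors (0.0562) and array weights (0.854). Hist1h2bg had the opposite direction, 93.8 against 81.6 TPM, and the 2 histone genes whose groups did not overlap were both lower. In neither list did a member pass over all genes or adjusted over the list alone. With the correction the adjusted p was 0.0342 for oxidative phosphorylation and 0.166 for histones among protein-coding genes, and 0.066 and 0.228 over all genes. Without hindlimb ischemia replicate 3 it was 0.433 for mitochondrially encoded genes (median 0.002), 0.145 for oxidative phosphorylation and 0.825 for histones, and without sham replicate 1 it was 0.501 and 0.287 for the latter lists, with medians of -0.06 for both.

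The lineage genes of the sorted population did not pass. Mpo had 11290 ± 1559 TPM in sham and 9846 ± 1922 TPM after hindlimb ischemia, and Elane had 10670 ± 1484 and 10710 ± 676 TPM. Elane's log2 fold change was 0.01, -0.11 with quantile normalization and 0.13 with size factors. Irf8 had 184 against 158 TPM, Csf1r 151 against 120 TPM, Cd34 277 against 219 TPM and Kit 110 against 93.7 TPM. These differences were under 1 SD of the sham libraries for Mpo, Elane, Irf8, Csf1r and Kit, and above it for Cd34 (SD 52.1). Neutrophil granule genes had a median of -0.12 (adjusted p 0.894), with Cd177 at -0.67 and Cxcr2 at -0.38. Monocyte genes had a median of -0.11 (adjusted p 0.433), with S100a4 at -0.51 and Ccr2 at 0.23. Stem and multipotent progenitor genes had -0.13 (adjusted p 0.213, and 0.0191 without sham replicate 3, within a range up to 0.53), and Gata2 in that list had 54.0 against 38.6 TPM and Tie1 5.15 against 3.35 TPM. The basophil, mast cell and eosinophil list, which holds Ear1 and Gzmb (log2 -0.51), had -0.06 (adjusted p 0.353). The dendritic list, with H2-DMa and H2-DMb1 at -0.20 and -0.17, had -0.01 (adjusted p 0.433). Lymphoid genes had -0.16 (adjusted p 0.193, and 0.0182 with no filter). One of them, Cd79a, was lower when adjusted over the list alone, with 2.11 against 0.756 TPM, and Cd79b had 48.3 against 44.0 TPM. Erythroblastic island macrophage genes had -0.09 (adjusted p 0.14), with C1qb at 1.78 against 0.897 TPM and Apoe at 78.5 against 59.2 TPM. Only 3 of 20 stromal and endothelial genes were expressed, under the minimum of 5 for a test, and Pdgfrb and Runx2 among them had log2 fold changes of -0.19 and -0.14. With size factors the medians of the monocyte, basophil and dendritic lists changed sign, to 0.01, 0.05 and 0.09, and with quantile normalization that of the dendritic list did, to 0.10.

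The lists of cell functions that did not pass included the G1/S genes (median -0.13, adjusted p 0.433), where Cdc6 had 44.9 against 32.8 TPM and Tipin 256 against 325 TPM. G2/M genes, with Bub1b and Kif20a at -0.25 and -0.22, had a median of -0.06 (adjusted p 0.564), or 0.07 (adjusted p 0.038) with the GC and length correction among protein-coding genes. Hypoxia and glycolysis genes had a median of -0.08 (adjusted p 0.513), which was 0.03 with size factors, and Kdm3a and Slc2a3 among them had -0.41 and -0.31. Interferon-stimulated genes had -0.06 (adjusted p 0.561), with Stat2 at -0.44 and Oas3 at -0.38. NADPH oxidase and antioxidant genes had -0.07 (adjusted p 0.752), or 0.04 with size factors, with Hmox1 at -0.43. Ribosomal protein genes had -0.01 (adjusted p 0.213), or 0.11 with size factors, with Rpsa and Rpl3 both at -0.16. This list was lower without sham replicate 1 (adjusted p 5.55e-08) and higher without sham replicate 2 (0.00058), sham replicate 3 (0.000694) or hindlimb ischemia replicate 1 (0.0239). Cholesterol synthesis genes had -0.18 (adjusted p 0.122), with Insig1 at -0.43 and Fdft1 at -0.38, and an adjusted p of 0.0417 without hindlimb ischemia replicate 1, within a range up to 0.825. Chromatin modifier genes had -0.18 (adjusted p 0.0877), with Kmt2a at -0.37 and Kdm6a at -0.32. They were lower and past 0.05 in 7 of 21 other settings, including no filter (0.0243), a mean of at least 5 TPM (0.0324), without sham replicate 3 (0.00577) and without hindlimb ischemia replicate 1 (0.0363). With each library left out in turn the adjusted p ran from 0.00577 to 0.902 and the median from -0.35 to -0.06. Receptor genes for growth factors, chemokines and adhesion had -0.17 (adjusted p 0.0927), with Ifnar1 at -0.42, and were lower and past 0.05 without sham replicate 2 (0.0168), sham replicate 3 (0.039) or hindlimb ischemia replicate 1 (0.0363), within a range of 0.0168 to 0.886 over the libraries left out. Angiogenic and paracrine factor genes had -0.18 (adjusted p 0.213), with Angpt1 at -0.36 and Mmp9 at -0.41, and the median ran from -0.30 to -0.07 with 1 library left out. For the neutrophil, basophil, dendritic, G2/M, interferon and ribosomal lists the median and mean were negative while camera, which compares a list with all other genes, gave the direction as higher. With size factors the medians of the G2/M and interferon lists became 0.05 and 0.03, and with quantile normalization 0.01 and 0.02. In these and the lineage lists, Cd79a was the only member to pass when adjusted over the list alone, and 0 passed over all genes.

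The authors' deposited table gives an adjusted p for 15747 genes, of which 34 lie under their threshold of 0.2, 10 higher and 24 lower after hindlimb ischemia. The authors' deposited table has 12 genes under 0.05, 3 higher and 9 lower. With unannotated models left out, the 3 highest log2 values, turned to hindlimb ischemia over sham, are in the authors' deposited table Tfrc at 0.75 (adjusted p 7.02e-06), Tgm1 at 0.60 (0.0305) and Gda at 0.49 (0.000951). The 3 lowest in the authors' deposited table are Gfi1b at -0.67 (0.00368), Banp at -0.65 (0.000607) and Zfp324 at -0.62 (0.000325). Herpud1, Syvn1 and Hspa8 have adjusted p of 0.000607, 0.000295 and 0.00951 in the authors' deposited table. Other genes named above do not pass in the authors' deposited table. Examples there are Hba-a1 at -0.22 (adjusted p 0.87), Hspa1a at -0.35 (0.62) and AF357399 at 0.28 (0.719). Their log2 fold changes in the limma fit were larger in size, at -1.87, -1.41 and 1.39, so the 2 measures are not alike for such genes. All 34 genes had the same direction in the limma fit. An unadjusted p under 0.05 was found there for 32 of them, and groups that did not overlap for 32. Both sets of values come from the same 6 libraries, so this match is not independent evidence. Zfp324, a zinc finger gene, had 10.4 ± 1.74 TPM in sham and 5.66 ± 0.733 TPM after hindlimb ischemia.

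The groups as wholes were not separated beyond other splits of the 6 libraries. Over the 500 most variable genes the mean distance between groups exceeded that within groups by 0.69 log2 units, a value reached by 3 of the 10 splits (one-sided exact permutation p = 0.3, where 0.1 is the smallest possible). Library deviations from the mean of all 6 followed GC content and transcript length across 10496 protein-coding genes, which are not independent replicates. Spearman's rho with GC content ran from -0.50 in hindlimb ischemia replicate 3 to 0.51 in sham replicate 3, and rho with length from -0.30 in sham replicate 2 to 0.50 in sham replicate 1. Hindlimb ischemia replicates 2 and 3 had negative values for GC content (-0.37 and -0.50), and replicate 1 a positive one (0.40). Once both trends were removed, the excess between groups was 1.35, the largest of the 10 splits (exact permutation p = 0.1).

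**Figure D3:**
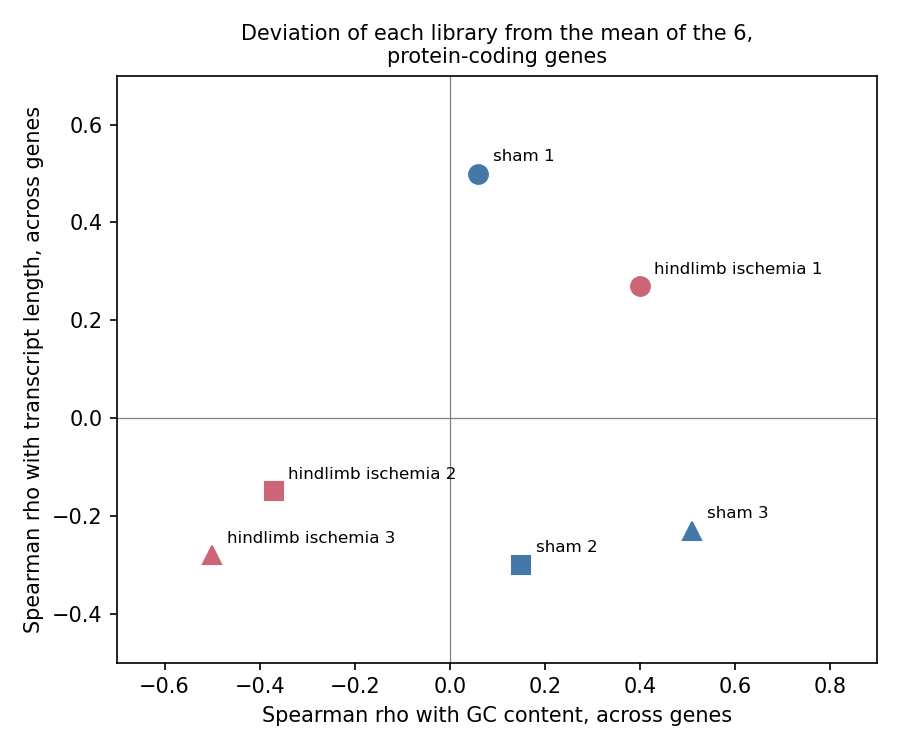
Spearman's rho across protein-coding genes between each library's deviation from the mean of the 6 and the gene's GC content (x axis) or transcript length (y axis). Sham libraries are in blue and hindlimb ischemia libraries in red; hindlimb ischemia replicate 1 lies with positive values on both axes, apart from replicates 2 and 3 of its group.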

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

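Size factors, protein-coding genes only, recovered reads, array weights, the GC and length correction and its combinations were chosen only after the result was seen; the other alternatives were fixed before the data were examined. Where no cause is named, the cause was not tested. With 0 genes past 0.05 under limma-trend (537 at an unadjusted p under 0.05), the count was also 0 with quantile normalization, no filter, a mean of at least 5 TPM, both other pseudocounts, size factors, protein-coding genes only, voom on recovered reads, the GC and length correction over all genes and the threshold of 0.2. It was 1 without a trend (0 higher, 1 lower), 1 with array weights (0 higher, 1 lower, Igkc) and 4 with the GC and length correction among protein-coding genes (2 higher, 2 lower). That last setting also tests fewer genes (10524). Leaving out 1 library gave 0 to 41 genes, with 0 to 24 higher and 0 to 17 lower. The 41 came without hindlimb ischemia replicate 1, and 1 gene each came without replicate 2 (Igkc) or replicate 3 (Mir1938) of that group.

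The replicate number as a block gave 69 genes past 0.05, 17 higher and 52 lower, and 513 past 0.2, with 9 lists past 0.05. Together with the GC and length correction among protein-coding genes it gave 9 genes (3 higher, 6 lower) and 7 lists, and together with voom on recovered reads 6 genes (1 higher, 5 lower) and 8 lists. Whether the numbers pair the samples is not settled. The deviations of same-numbered libraries correlated at 0.39, 0.18 and 0.08, so pairs 1 and 2 lay above the threshold of 0.1 and pair 3 below it. Sham replicates 1 and 3 and hindlimb ischemia replicates 1 and 2 correlated best with their own number. Sham replicate 2 was closest to hindlimb ischemia replicate 3, and hindlimb ischemia replicate 3 to sham replicate 2.

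The count of 7 lists past 0.05 became 4 with quantile normalization, 4 with array weights, 2 with the GC and length correction over all genes, 4 with it among protein-coding genes, 0 with an estimated correlation and 0 with fry. Leaving out 1 library gave 2 lists (without hindlimb ischemia replicate 3) to 11 (without hindlimb ischemia replicate 1), and 4 without sham replicate 1. Immediate early and heat shock genes and erythroid and megakaryocyte genes were past 0.05 and lower in all 21 camera settings with the preset correlation, with adjusted p up to 4.89e-06 and 0.00292. Mitochondrially encoded genes passed in 17 of 21, oxidative phosphorylation genes in 15, histones and inflammatory genes in 13 each and unfolded protein response genes in 11. Separation of the groups was 0.49 to 1.35 under its alternatives, with exact permutation p of 0.1 to 0.4.

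Of 1505 comparisons of the 74 named genes with an alternative, 1451 left the direction and the side of the threshold as they were, 41 brought one of 19 genes past 0.05, and 13 reversed a direction in 4 genes. Of 547 for the 24 lists, 424 were the same, 23 newly passed (7 lists), 47 no longer passed and 53 reversed (12 lists), where the test gives the direction and the values below are medians. The genes that reversed passed under no setting. Pdgfrb was 0.029 with the GC and length correction, 0.033 among protein-coding genes and 0.033 with the block added; Runx2 was 0.043 with array weights and 0.038, 0.048 and 0.048 under those 3 corrections. Elane was -0.108 with quantile normalization, -0.121 with array weights and -0.059 to 0.123 with 1 library left out, and Kit -0.433 to 0.006. Leaving out 1 library also changed the size of values that kept their sign. Angpt1 ran from -0.566 to -0.132, Mmp9 from -0.606 to -0.167, Kdm3a from -0.617 to -0.173 and Slc2a3 from -0.497 to -0.169. Likewise Bub1b ran from -0.483 to -0.070, Kif20a from -0.399 to -0.082, Oas3 from -0.554 to -0.161 and Pdgfrb from -0.419 to -0.036.

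With quantile normalization the neutrophil list (-0.110) and the ribosomal list (-0.014) reversed. Without the filter the neutrophil (-0.122), G2/M (-0.063) and interferon (-0.056) lists did, and with a mean of at least 5 TPM the NADPH list (-0.053). Hypoxia genes were 0.032 and NADPH genes 0.043 with size factors, -0.083 and -0.068 among protein-coding genes, and 0.032 and 0.045 with voom on recovered reads. NADPH genes were 0.045 with the block and voom. Array weights reversed the neutrophil (-0.166), stem (0.007), dendritic (-0.026), G1/S (-0.074), interferon (-0.123), ribosomal (-0.100) and histone (-0.039) lists. The GC and length correction over all genes reversed G1/S (-0.004), hypoxia (0.035) and NADPH (0.022) genes. Among protein-coding genes it gave 0.005, 0.038 and 0.022 for these and -0.054 for the basophil list, and with the block added 0.005, 0.038 and 0.022. Fry reversed the neutrophil (-0.122), basophil (-0.058), dendritic (-0.008), G2/M (-0.063), interferon (-0.061) and ribosomal (-0.013) lists, since it tests against 0 and not against other genes.

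With 1 library left out, medians ran from -0.179 to 0.007 for neutrophil, -0.141 to 0.003 for basophil, -0.129 to 0.071 for dendritic, -0.256 to -0.024 for G1/S, -0.115 to 0.015 for G2/M, -0.185 to 0.006 for hypoxia and -0.060 to 0.059 for oxidative phosphorylation genes. They ran from -0.126 to 0.023 for interferon, -0.126 to -0.033 for NADPH, -0.117 to 0.058 for ribosomal and -0.064 to 0.124 for histone genes. Medians that kept their sign ran from 0.002 to 0.507 for mitochondrially encoded, -0.319 to -0.103 for inflammatory, -0.243 to -0.027 for unfolded protein response, -0.518 to -0.338 for immediate early and heat shock, -0.479 to -0.272 for erythroid and megakaryocyte, -0.350 to -0.057 for chromatin and -0.304 to -0.069 for angiogenic genes. The sign was also kept by the medians of monocyte (-0.158 to -0.062), lymphoid (-0.168 to -0.072) and stem (-0.311 to -0.039) genes. It was kept as well for erythroblastic island macrophage (-0.275 to -0.096), cholesterol (-0.282 to -0.075) and receptor (-0.276 to -0.085) genes. Ribosomal protein genes passed in opposite directions, lower without sham replicate 1 (adjusted p 5.55e-08) and higher without sham replicate 2 (0.00058) or 3 (0.000694), within a range of 5.55e-08 to 0.976. Genes with few reads, such as Mir1938, Mir695 and mmu-mir-6942 with 0 reads in at least 1 library, are limited by depth.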

Other observations

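The tests of explanations and of other splits in this part, and the fit with array weights, were chosen only after the result was seen, while leaving out each library was fixed before the data were examined. Without hindlimb ischemia replicate 1, mitochondrial tRNA genes were among the genes past 0.05, with log2 fold changes of 1.59 for mt-Tn, 1.01 for mt-Tc and 1.24 for mt-Ti, together with the globin genes Hba-a1 (-1.24), Hba-a2 (-1.23) and Hbb-bs (-0.94). Over all 6 libraries the tRNA values were 0.87 for mt-Tn, 0.49 for mt-Tc and 0.87 for mt-Ti, each with an adjusted p of 0.874. Igkc, an immunoglobulin gene of B lineage cells, had a log2 fold change of -3.49 with array weights and -3.75 without hindlimb ischemia replicate 2. Its values were 49.4, 38.6 and 34.9 TPM in sham replicates 1 to 3 and 1.46, 49.7 and 2.88 TPM in hindlimb ischemia replicates 1 to 3, so replicate 2 of that group lay with sham, and the log2 fold change over all 6 libraries was -2.41 (adjusted p 0.874).

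Immediate early and heat shock genes were lower after hindlimb ischemia by camera with a preset correlation, a call lost with an estimated one (adjusted p = 0.8 with an estimated correlation). Trends with GC content and transcript length are argued against as the whole cause, since the list kept an adjusted p of 2.78e-12 at the preset correlation and a median of -0.30 after both trends were removed. The immediate early genes of the list respond within minutes to handling. A difference in handling of the bone marrow before lysis may explain some of the 10 members whose groups did not overlap. Those 10 also include the constitutive gene Hspa8. Handling and treatment cannot be told apart here, because the labels give no record of handling that crosses the groups. An effect of hindlimb ischemia itself stays open as untested. The median relative to all genes was 0.331 in size for the real grouping, as large in 1 of the 10 splits, and 0.199 for the highest other, but 10 splits are too few for a share under 0.05. The list was also picked after its value in the real grouping was seen, which favors a high rank.

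By camera with a preset correlation erythroid and megakaryocyte genes were lower after hindlimb ischemia (adjusted p = 0.269 with an estimated correlation), and with the GC and length trends removed the preset adjusted p was 2.62e-06, which argues against those trends as the whole cause. Carry-over of erythroid cells or their RNA into sham libraries is a candidate explanation, since the 4 globins had a median of -1.71 and the 12 other members -0.31. How far the sort removed such cells was not tested. Igkc, a gene of B lineage cells, was also present in the sham libraries. It was as high in hindlimb ischemia replicate 2, so it did not mark the sham libraries alone. In hindlimb ischemia replicate 1, the library with the lowest globins (median 3.5 TPM against 17.8 and 13.8), the 12 others differed from the other replicates by a median of 0.04 (SD 0.41; 7 of 12 higher), which in a single library decides nothing, so carry-over cannot be told apart from a change in the progenitors. An effect of hindlimb ischemia stays open as untested. The relative median was 0.288 in size for the real grouping, as large in 1 of the 10 splits, and 0.279 for the highest other, and 10 splits are too few for a share under 0.05. This list too was picked after its value in the real grouping was seen.

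The libraries parted more strongly across the groups than between them. Sham replicates 1 and 3 with hindlimb ischemia replicate 1, set against sham replicate 2 with hindlimb ischemia replicates 2 and 3, gave 1209 genes past 0.05 and 2128 among protein-coding genes alone, against 0 for the real grouping, which points to a structure of the samples. With GC content and transcript length trends removed, 0 genes were left in that split, in line with such trends as its cause. For the number of genes the real value was 0, which 10 of the 10 splits reach by construction, so that count decides nothing. With the correction the real value was 4, reached by 1 split, and the highest other 1. For the number of lists the real value was 7, reached by 7 of the 10 splits, and the highest other 11. After the correction among protein-coding genes the real grouping gave 4 lists, and other splits up to 11. For these counts 10 splits are too few for a share under 0.05.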
